A study of Homo sapiens with 30 samples.

How the data were processed

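RNA was measured in OPM2 and H929, 2 human multiple myeloma cell lines, after 24 h with 100 nM dBRD9-A or with the solvent DMSO. Each of the 4 groups holds 3 libraries, so 12 libraries were used. Per the labels' protocols, RNA was taken with a Qiagen column kit and libraries were made with a stranded, poly(A)-selecting Illumina kit. Another 18 of the 30 samples listed, made with hairpins against BRD9 or luciferase in both lines or from OPM2 polysomes, were not analysed here.

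Per the submitters' processing notes, the tools include STAR and featureCounts and the builds hg19 and GRCh37, with no versions given. Per the file headers, each file gives 51780 RefSeq transcripts with a count, an FPKM and a TPM value, under 25680 gene symbols. The deposited counts are whole numbers that were not normalised, and a read was counted for every transcript of a gene that it overlapped. The strand setting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The deposited FPKM values divide the count by transcript length and by the column total, and served only to recover the length. The deposited TPM values were compared with the counts and used for nothing else. The files list no mitochondrially encoded genes. Because the reference at hand is of another build, no coordinates are given, and it was used only for GC content, older gene symbols and the host genes of small nucleolar RNAs. A GC value was found for 98.07% of the genes tested.

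Each gene was represented by the transcript with the highest mean count over the 12 libraries. Totals over these genes, in replicates 1, 2 and 3, were 62661302, 70314742 and 76600945 counts in OPM2 with DMSO, 62009396, 24524193 and 61036784 in OPM2 with dBRD9-A, 65679820, 61187063 and 58418879 in H929 with DMSO and 48589834, 42895389 and 60126395 in H929 with dBRD9-A. Between 13439 and 15441 genes had at least 10 counts in a library. Genes were filtered with filterByExpr by group, which left 16408, and scaled with TMM factors. Changes were tested in R 4.3.3 with edgeR 4.0.16, a quasi-likelihood test with a mean per group and 1 spread per gene over all 4 groups, which leaves 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The comparison of the lines in DMSO also required an absolute log2 fold change of at least 1. The other comparisons were dBRD9-A against DMSO in each line and the difference of these responses, H929 minus OPM2. CPM values are scaled by the TMM factors and given as mean ± SD. Log2 CPM values use a prior count of 0.25. A fold change against a group without a single count is given as a lower bound against 3 counts over the group, and such bounds cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

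Before the data were examined, 36 gene lists were fixed and the tests, the main alternatives and a rule for naming genes were set. 35 lists had at least 3 tested members, and the list of mitochondrially encoded genes had none in the files. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists. The rule named BRD9, GLTSCR1, GLTSCR1L, BRD7, CRBN, MYC, IRF4, IKZF1 and IKZF3 and, per treatment, the 8 highest and 8 lowest called genes whose treated and DMSO libraries did not overlap and whose mean was at least 1 log2 CPM. It also named up to 4 called members of each list, or 2 uncalled ones where none was called, and the 8 highest and 8 lowest genes called in both lines. For the difference of the responses it named the 5 highest, the 5 lowest and called list members, and for the lines in DMSO the 8 highest on each side and a fixed set of myeloma genes. The rule gave 142 genes in OPM2, 128 in H929, 19 for the difference of responses and 25 for the lines in DMSO. From these the text takes 34, 37, 19 and 12. In the treatment comparisons and in DMSO the choice among the genes of the rule was made after their values were seen. FGFR3 in the treatment comparisons lies outside the rule and was also chosen after its values were seen. Of the genes tested with a mean of at least 20 counts, 139 had counts within 5% of those of another symbol in every library, and none of them is named here.

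The alternatives planned were RLE factors, library size without scaling, DESeq2 1.42.0, no low-count filter, a filter of 1 CPM in 3 libraries, each line fitted alone, each library left out, the replicate number as a block, and removal of a smooth trend with transcript length. Those added after the data were seen were removal of a trend with transcript GC content, the sum over transcripts, limma-voom with a weight per library, the length trend for the other results, and OPM2 dBRD9-A replicate 2 left out of the comparisons that do not contain it. Every count was also compared with other splits of the same libraries, all 10 for 3 against 3 and 100 drawn of 200 for both lines together.

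The procedure was tested on simulated counts with 200 changed genes per comparison. At 2-fold changes it recovered 47.8% of them in OPM2, 44.8% in H929, 16.4% for the difference of responses and 43.3% for the lines in DMSO. At 4-fold changes these shares were 83.3%, 84.8%, 56.1% and 86.4%. At 1.5-fold changes they were 13.4%, 11.9%, 1.49% and 7.46%. False calls numbered 10, 7, 4 and 7 among 106, 101, 53 and 98 genes called, in each comparison a share above the 5% aimed at. For the lines in DMSO the simulated calls used the adjusted p alone. The fold threshold was not applied there, so these shares do not describe the full rule of that comparison. A list lowered 1.5-fold was found in each line, with 1 other list called, which shares genes with it. Genes were drawn independently of each other there, so this does not test camera on genes that vary together. In the data the lowered list, the ribosome biogenesis factors, had an estimated correlation of 0.317 in OPM2 and 0.306 in H929.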

Results

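The study asked how the transcripts of OPM2 and H929 cells respond to dBRD9-A, a compound that degrades BRD9, the bromodomain subunit of the non-canonical BAF chromatin remodelling complex. Both are multiple myeloma lines. OPM2 dBRD9-A replicate 2 stood apart from the other libraries, with 24524193 counts against 42895389 to 76600945. The SD of its log2 deviation from its group mates was 0.79 over 9281 genes, and its deviations correlated with transcript GC content across genes (Spearman -0.70). In the 9 libraries of the other groups this SD was 0.11 to 0.24. Replicates differed by more than the sampling of reads gives, with a chi-square per degree of freedom of 16.9 to 48.1 between pairs without replicate 2 and of 255 and 287 between it and its group mates. Deviations of H929 dBRD9-A replicates 1 and 2 also correlated with GC content (Spearman -0.63 and 0.65). The SD of the trend with GC content was 0.12 and 0.15 in these, against 0.56 in OPM2 dBRD9-A replicate 2.

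**Figure D1:**
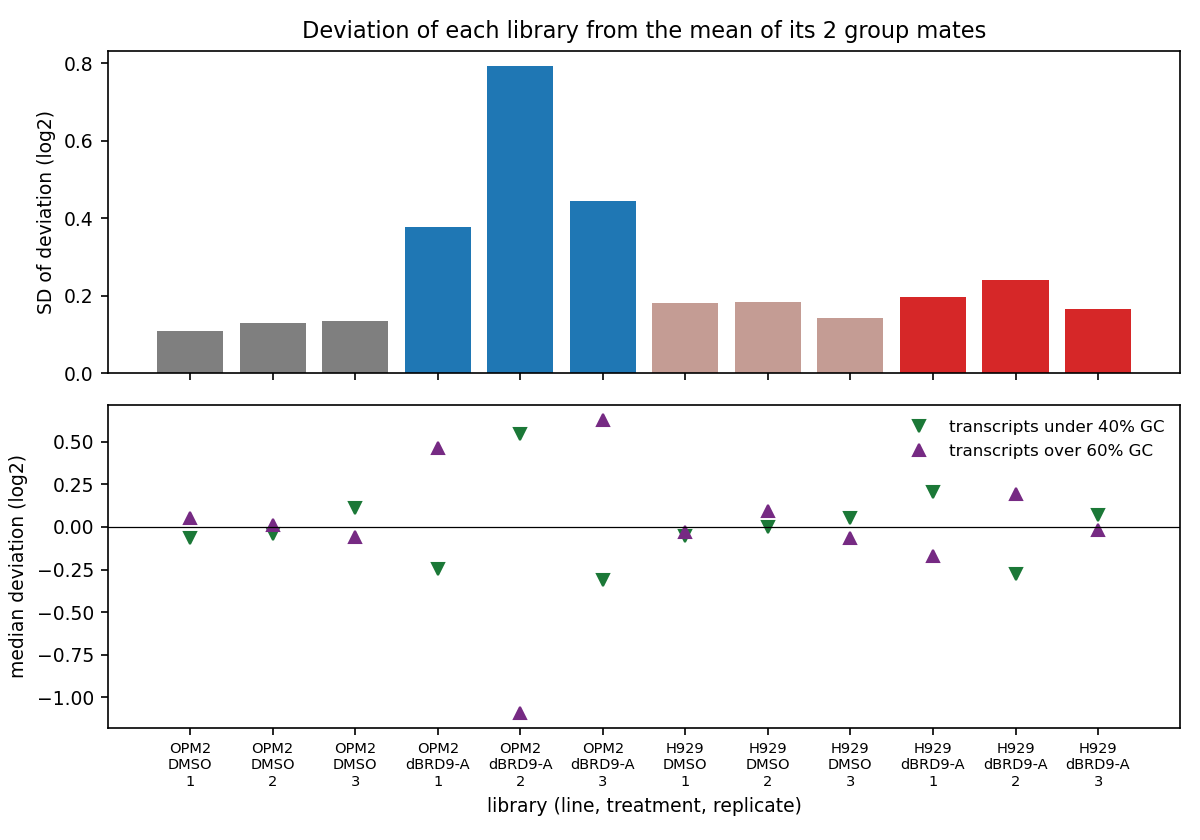
Upper panel, SD of each library's log2 deviation from the mean of its 2 group mates; lower panel, median log2 deviation of transcripts under 40% and over 60% GC. OPM2 dBRD9-A replicate 2 has an SD of 0.79 and medians of 0.55 and -1.09, and it is part of the mean against which its group mates are drawn.

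In OPM2, dBRD9-A lowered MYC and a broad set of genes for making ribosomes, and raised genes of the type I interferon response. MYC, a transcription factor that drives growth, went from 291.2 ± 6.40 to 115.4 ± 18.9 CPM (SD, n = 3). UBE2J1, a ubiquitin-conjugating enzyme of the endoplasmic reticulum, went from 695 ± 83.1 to 187 ± 46.1 CPM. PARP14, an ADP-ribosyltransferase of the interferon response, went from 2.18 ± 0.29 to 29.8 ± 8.28 CPM. The log2 fold changes were -1.33 ± 0.26 (SE), -1.89 ± 0.16 and 3.77 ± 0.24, with edgeR adjusted p of 0.00544, 2.98e-05 and 1.02e-05.

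The count of genes called in OPM2 was 2857 of 16408, 1652 higher and 1205 lower, with 809 and 243 of them changed at least 2-fold. Scaled by library size alone, 69.4% of the called genes were higher, against 57.8% here. Without OPM2 dBRD9-A replicate 2 the count was 5277. It was 1529, 1381 and 1489 without DMSO replicates 1, 2 and 3, and 871 with the OPM2 libraries fitted alone. It was 1729 with the replicate number as a block, 4346 with the GC trend removed and 7243 with limma-voom. Across 9281 genes the OPM2 log2 fold changes correlated with transcript GC content (Spearman -0.39), and without replicate 2 this was -0.0016.

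The transcript of BRD9 itself was at 89.7 ± 4.02 CPM in DMSO and 76.3 ± 8.04 with dBRD9-A in OPM2, and was not called (log2 fold change -0.23, edgeR adjusted p = 0.241; limma-voom called it, with adjusted p = 0.0124). GLTSCR1L, another subunit found only in this complex, rose from 36.8 ± 1.41 to 70.9 ± 9.91 CPM. GLTSCR1 had a log2 fold change of 0.22 and was not called, and was called without replicate 2 (0.37), with the GC trend removed (0.79) and with limma-voom (0.31). BRD7, the bromodomain subunit of a sister complex, had 0.44, which became -0.14 without replicate 2. CRBN, the cereblon gene, had 0.02. Of the lymphoid transcription factors, IRF4 had -0.62 with adjusted p = 0.0643, IKZF1 had 0.27 and IKZF3 had 0.01, and IRF4 was called in 5 and IKZF1 in 2 of 17 alternatives.

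Among the fixed lists, 45 of 63 MYC-associated genes fell in OPM2 and none rose, with a median log2 fold change of -0.78 (camera adjusted p = 5.8e-22, and adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone, 49 fell and 1 rose. SRM, spermidine synthase, fell by 1.09, and HK2, a hexokinase, fell by 0.99 on the log2 scale. Of 139 ribosome biogenesis factors 67 fell and 1 rose, and adjusted over the list alone 73 fell and 1 rose (camera adjusted p = 2.21e-16, and adjusted p = 0.292 with an estimated correlation). RRP9 and RRP12, which act in ribosomal RNA processing, fell by 1.22 and 1.20. In the RNA polymerase I and III machinery 10 of 41 genes fell and 1 rose, with POLR1E at -0.83 (adjusted over the list alone, 13 and 1; camera adjusted p = 7.12e-05, and adjusted p = 0.292 with an estimated correlation). Without replicate 2, 59, 120 and 19 members of these 3 lists fell. Their medians were then -0.70, -0.56 and -0.26, against -0.78, -0.41 and -0.35 with it. Of 81 cytosolic ribosomal protein genes 1 fell, with a median of -0.09 (camera adjusted p = 0.0683); without replicate 2, 8 fell and camera gave adjusted p = 5.43e-05, against adjusted p = 0.675 with an estimated correlation.

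Of 49 S-phase genes 20 fell in OPM2, with MCM10, a replication initiation factor, at -0.69 (adjusted over the list alone, 27 fell; camera adjusted p = 2.84e-08, and adjusted p = 0.292 with an estimated correlation). Of 47 mitosis genes 1 rose and 1 fell. Of 24 glycolysis genes 12 fell and 1 rose (adjusted over the list alone, 16 and 2), and of 24 cholesterol biosynthesis genes 9 fell (adjusted over the list alone, 11). INSIG1, a sterol sensor, fell by 1.23. Their camera adjusted p were 6.54e-06 and 1.97e-05, and adjusted p = 0.292 and adjusted p = 0.299 with an estimated correlation. Of 45 genes of the unfolded protein response 12 fell and 2 rose (adjusted over the list alone, 18 and 2), and of 29 ATF4 targets 9 fell and 1 rose (adjusted over the list alone, 13 and 1). ASNS, asparagine synthetase, fell by 1.22. Camera gave adjusted p = 0.000398 and 1.97e-05 for them, and adjusted p = 0.292 and adjusted p = 0.299 with an estimated correlation. Glycolysis, cholesterol, unfolded protein and ATF4 lists had 15, 13, 23 and 16 lower genes without replicate 2. Their median log2 fold changes were then -0.36, -0.33, -0.30 and -0.47, against -0.49, -0.38, -0.28 and -0.47 with it, so more calls did not mean larger falls.

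Of 43 interferon response genes 24 rose in OPM2 and none fell, with a median log2 fold change of 1.34, also without the 4 members at or under 3 counts in each group (adjusted over the list alone, 26 rose; camera adjusted p = 2.7e-17, and adjusted p = 0.134 with an estimated correlation). IFIT3 went from 0.77 ± 0.24 to 11.6 ± 7.86 CPM, PARP9 from 2.34 ± 0.50 to 23.8 ± 9.72, OAS2 from 0.78 ± 0.03 to 4.05 ± 0.36 and LGALS3BP from 0.05 ± 0.04 to 5.86 ± 2.67. Without replicate 2, 25 rose. Of 25 plasma cell genes 5 fell (adjusted over the list alone, 7; camera adjusted p = 0.000128, and adjusted p = 0.292 with an estimated correlation). They include IGJ, the antibody joining chain, at -1.55, SLAMF7, a surface receptor, at -1.63, and MZB1 at -1.57. Of 8 stromal and epithelial genes 4 rose (adjusted over the list alone, 5; camera adjusted p = 0.00135, and adjusted p = 0.292 with an estimated correlation), with FN1, fibronectin, from 15.7 ± 2.57 to 60.7 ± 5.75 CPM. The stromal and epithelial list holds 20 genes, and its called members other than FN1 had at most 0.41 CPM in any OPM2 library. Without replicate 2, 8 plasma cell genes fell and 3 rose, and 5 stromal and epithelial genes rose.

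Further genes at the lower end of the range in OPM2 were UNC13C at -2.78, FJX1 at -2.65, OAF at -2.48 and ABCG2, a drug efflux pump, at -2.36. BMF, a pro-apoptotic BCL2 family member, rose by 1.61, CD68, a lysosomal marker of macrophages, by 2.79 and VCL, vinculin, by 0.96. FGFR3, chosen after its values were seen, went from 2112 ± 62.5 to 714 ± 372 CPM (-1.56, adjusted p = 0.00553; 1 of 17 alternatives ended this call).

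**Figure D2:**
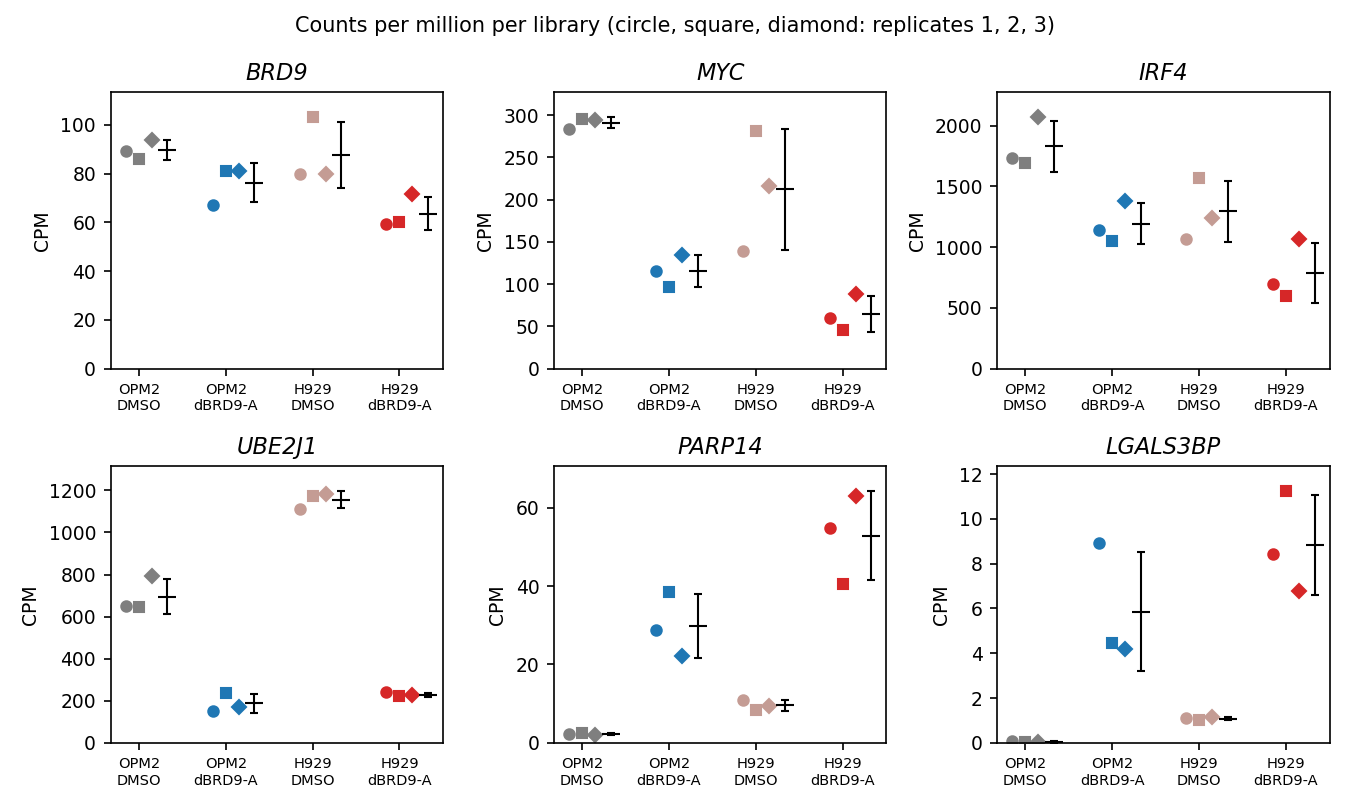
CPM of 6 genes in each library, with the mean and SD of each group of 3 beside the points. MYC and UBE2J1 lie lower, and PARP14 and LGALS3BP higher, in all 3 treated libraries of each line than in the 3 DMSO libraries.

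In H929, dBRD9-A again lowered MYC and genes for making ribosomes and raised interferon response genes. MYC went from 212 ± 71.6 to 64.5 ± 21.3 CPM (SD, n = 3; log2 fold change -1.72 ± 0.26 SE, edgeR adjusted p = 0.00183). UBE2J1 went from 1155 ± 40.02 to 229 ± 9.50 CPM and PARP14 from 9.54 ± 1.33 to 52.8 ± 11.4. CCND2, cyclin D2, went from 28.2 ± 9.07 to 5.83 ± 1.72 CPM.

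In all 2134 of 16408 genes were called in H929, 1203 higher and 931 lower, with 650 and 138 of them changed at least 2-fold. Scaled by library size alone, 71.8% were higher, against 56.4% here. With OPM2 dBRD9-A replicate 2 left out, which enters through the spread shared by all groups, the count was 5946, and it was 4970 with the H929 libraries fitted alone. It was 812 and 1060 without H929 DMSO replicates 2 and 3, and 894 and 1316 without H929 dBRD9-A replicates 1 and 2. It was 1112 with the replicate number as a block, 3670 with the GC trend removed and 5910 with limma-voom.

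BRD9 went from 87.7 ± 13.5 to 63.6 ± 6.80 CPM in H929 (-0.46, edgeR adjusted p = 0.0391), a call that 10 of 18 alternatives ended, among them the replicate block (adjusted p = 0.108). GLTSCR1L rose by 0.54, a call that 1 of 18 ended. GLTSCR1 had 0.27, and was called without OPM2 dBRD9-A replicate 2. BRD7 had -0.13, CRBN -0.04 and IKZF3 -0.04. IKZF1 rose by 0.56. IRF4 had -0.72 with adjusted p = 0.045, a call that 10 of 18 alternatives ended, among them the block (adjusted p = 0.0695).

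Of the 63 MYC-associated genes 44 fell in H929 and none rose, with a median of -0.69 (adjusted over the list alone, 51 fell; camera adjusted p = 6.7e-26, and adjusted p = 0.144 with an estimated correlation). Of 139 ribosome biogenesis factors 72 fell and none rose, with a median of -0.59 (adjusted over the list alone, 103; camera adjusted p = 7.48e-30, and adjusted p = 0.144 with an estimated correlation). PPAN and TCOF1, factors of ribosome assembly and ribosomal RNA synthesis, fell by 0.87 and 0.83, and SRM by 0.92. In the RNA polymerase I and III machinery 11 of 41 fell, with POLR1E at -0.88 (adjusted over the list alone, 12 fell and 1 rose; camera adjusted p = 2.15e-07, and adjusted p = 0.144 with an estimated correlation). Of 81 cytosolic ribosomal protein genes none was called by edgeR or adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.089). Of 49 S-phase genes 20 fell, with MCM10 at -0.71 and CCNE1, cyclin E1, at -0.73 (adjusted over the list alone, 23; camera adjusted p = 1.4e-11, and adjusted p = 0.144 with an estimated correlation). In H929 without OPM2 dBRD9-A replicate 2, 57 MYC-associated genes, 125 biogenesis factors, 26 polymerase genes and 38 S-phase genes fell.

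Of 43 interferon response genes 24 rose in H929 and none fell, with a median of 1.40 (adjusted over the list alone, 27; camera adjusted p = 6.7e-26, and adjusted p = 0.0469 with an estimated correlation). DTX3L, a partner of PARP9, went from 2.94 ± 0.35 to 19.8 ± 1.56 CPM, IFIT5 from 0.96 ± 0.18 to 6.41 ± 1.097 and LGALS3BP from 1.08 ± 0.07 to 8.82 ± 2.24. Without OPM2 dBRD9-A replicate 2, 33 rose and 1 fell, with adjusted p = 0.229 with an estimated correlation. Of 28 replication-dependent histone genes 6 rose, HIST2H2BE by 1.24 (adjusted over the list alone, 9; camera adjusted p = 0.000177, and adjusted p = 0.404 with an estimated correlation). Of 8 stromal and epithelial genes 4 rose, FN1 by 1.38 (adjusted over the list alone, 5; camera adjusted p = 3.03e-07, and adjusted p = 0.144 with an estimated correlation). Of 25 plasma cell genes 4 fell and 1 rose (adjusted over the list alone, 5 and 1; camera adjusted p = 0.187), with IGJ at -1.14 and SLAMF7 at -0.62, the latter lost in 5 of 18 alternatives. Without OPM2 dBRD9-A replicate 2, 12 histone genes and 5 stromal and epithelial genes rose.

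Further genes that rose in H929 were TNS1, tensin 1, at 3.83, SYNPO, synaptopodin, at 3.67, SLC7A8, an amino acid transporter, at 2.95 and TMEM173, the gene of STING, at 2.93. FJX1 fell by 2.75, CELSR2 by 2.20, MYB, a transcription factor, by 1.80 and STC2 by 1.28. BMF rose by 0.98, CD68 by 1.19, CAV1, caveolin 1, by 1.31 and VCL by 0.92. FGFR3, chosen after its values were seen, went from 85.0 ± 6.91 to 33.8 ± 0.998 CPM (-1.33, adjusted p = 0.0144; 5 of 18 alternatives ended this call).

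**Figure D3:**
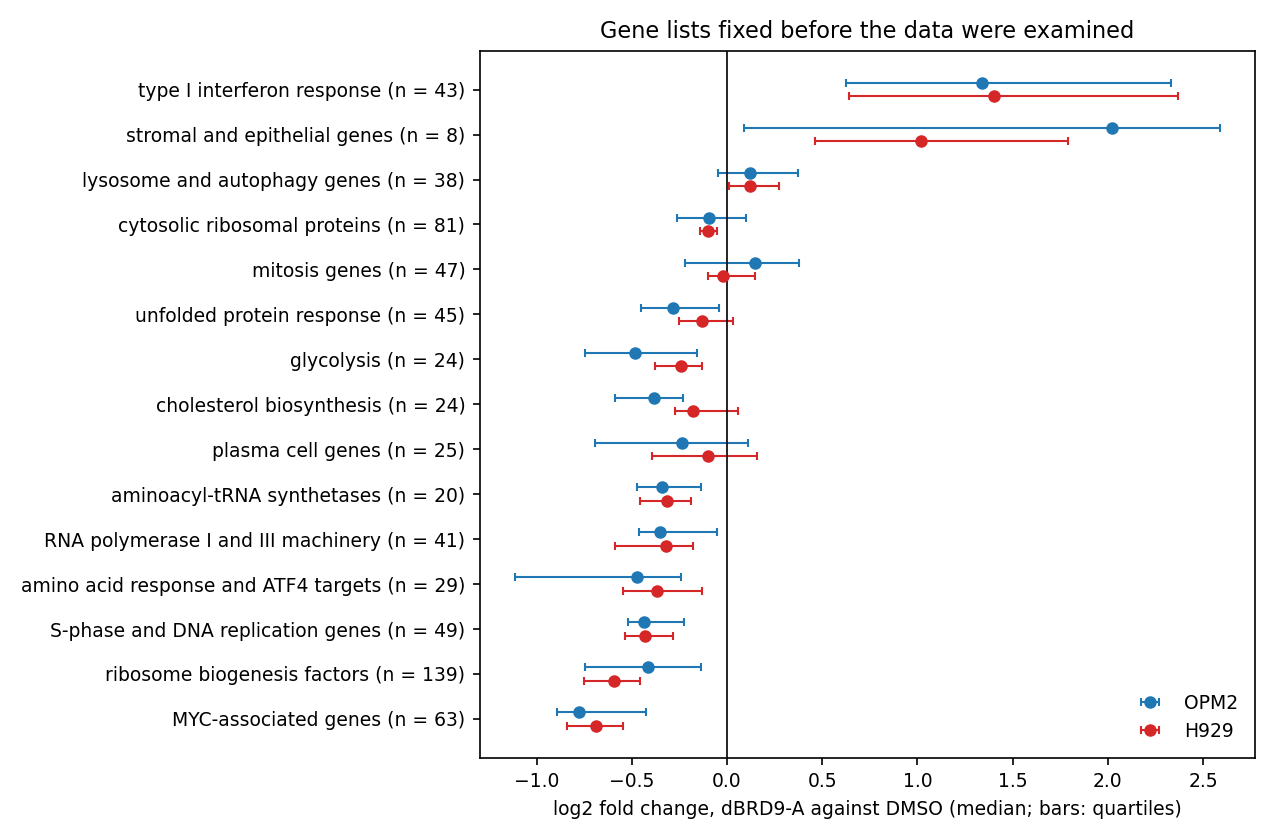
Median log2 fold change of the tested genes of 15 of the 36 fixed lists in each line, with bars from the lower to the upper quartile. MYC-associated genes have medians of -0.78 in OPM2 and -0.69 in H929, and interferon response genes 1.34 and 1.40.

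Many of the genes that changed were shared by the lines. Called in both and in the same direction were 1142 genes, among them MYC, UBE2J1, FJX1, IGJ, PARP14, LGALS3BP, FN1 and BMF. Of these 619 were higher, where independent lists would share 121, and 523 were lower, where they would share 68.4. The odds ratios were 14.5 (95% interval 12.7 to 16.6) and 27.8 (23.9 to 32.4), by Fisher's exact test, two-sided, over 16408 genes, which are not independent of each other. Called in opposite directions were 18 genes. Across all genes tested, the log2 fold changes correlated with Pearson's r of 0.52 and a Spearman correlation of 0.56. The lines share no DMSO library, but they share the spread of each gene.

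Without OPM2 dBRD9-A replicate 2, 3352 genes were shared. The count was 718, 660 and 683 without OPM2 DMSO replicates 1, 2 and 3, 489 and 632 without H929 DMSO replicates 2 and 3, and 525 without H929 dBRD9-A replicate 1. It was 574 with the replicate number as a block, 2128 with the GC trend removed, 1789 with DESeq2 and 3962 with limma-voom. Scaled by library size alone, 71.5% of the shared genes were higher, against 54.2% here.

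**Figure D4:**
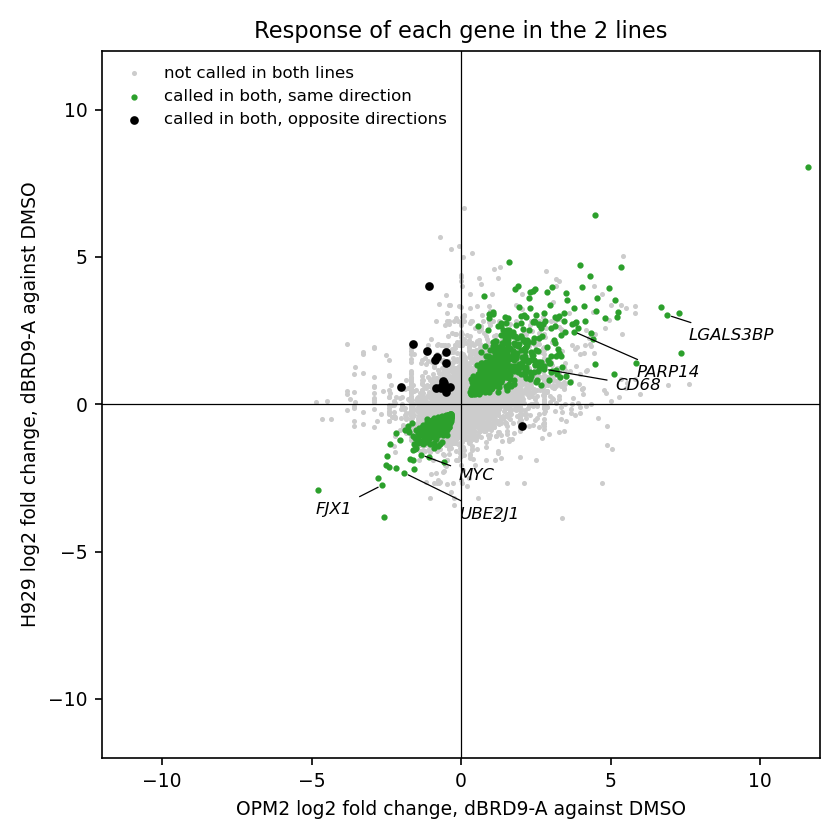
Log2 fold change of each gene tested in OPM2 (horizontal) and H929 (vertical), with genes called in both lines in the same direction in green and in opposite directions in black. The 1142 green points include 619 higher and 523 lower genes, and 18 points are black.

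The size of the response differed between the lines for some genes. OAS2, an interferon-induced sensor of double-stranded RNA, rose in OPM2 from 0.78 ± 0.03 to 4.05 ± 0.36 CPM, while in H929 it was at 66.0 ± 1.77 in DMSO and 79.7 ± 24.7 with dBRD9-A (H929 minus OPM2 response -2.10 ± 0.27 SE, edgeR adjusted p = 0.0053, n = 3 per group). ABCG2 fell in OPM2 from 8.03 ± 1.86 to 1.52 ± 0.44 CPM, and was at 2.80 ± 0.26 and 3.69 ± 0.07 in H929 (2.76 ± 0.31, adjusted p = 0.00347). SYNPO was at 5.19 ± 1.45 and 8.82 ± 2.43 CPM in OPM2, and rose from 1.103 ± 0.06 to 14.1 ± 2.14 in H929 (2.90 ± 0.34). CYSLTR1, a leukotriene receptor, went from 0.16 ± 0.06 to 5.85 ± 2.14 CPM in OPM2 and from 49.6 ± 9.33 to 101.1 ± 28.0 in H929 (-4.09 ± 0.48).

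The interaction test called 95 genes, 48 with the higher response in H929 and 47 with the higher response in OPM2. SH3PXD2B (2.60), AFAP1L2 (2.37), PTGER4, a prostaglandin receptor (2.28), and HBD, delta globin (2.09), had the higher log2 response in H929. COL27A1 (-3.12), APOBEC3F (-2.53), PSD3 (-2.46) and CDC14B (-2.38) had the higher one in OPM2. Of the 43 interferon genes DTX3L had the higher response in H929 and OAS2, LGALS3BP and UBE2L6 in OPM2 (adjusted over the list alone, 2 and 7; camera adjusted p = 0.169). Calls for COL27A1, AFAP1L2, CDC14B, LGALS3BP, UBE2L6, DTX3L, CFLAR, CAV1, CD68, HBD and ITGA3 were lost in 10, 7, 1, 6, 11, 11, 9, 13, 2, 14 and 13 of 22 alternatives. The count was 507 without OPM2 dBRD9-A replicate 2, 372 with DESeq2, 224 with the GC trend removed, 882 with limma-voom and 26 with the replicate number as a block. Leaving out any of 10 other libraries, all but OPM2 dBRD9-A replicate 3, moved it to between 35 and 54.

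In DMSO the lines differed in many genes, including those of known myeloma subtypes. CCND1, cyclin D1, was at 0.07 ± 0.04 CPM in OPM2 and 190.5 ± 26 in H929, while CCND2 was at 2058 ± 472 and 28.2 ± 9.07 (SD, n = 3). FGFR3 was at 2112 ± 62.5 and 85.0 ± 6.91 CPM. WHSC1, a histone methyltransferase, was at 1930 ± 138 and 1060 ± 42.6, a difference under the fold threshold of this comparison. NRAS was higher in H929 (107.1 ± 4.36 and 730 ± 37.4 CPM), and MAF was at 54.96 ± 7.95 and 179 ± 12.6.

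The edgeR test called 5960 genes between the lines, 3505 higher and 2455 lower in H929 (H929 minus OPM2 log2 fold change 11.46 for CCND1, -6.19 for CCND2, -4.63 for FGFR3, 2.77 for NRAS and 1.71 for MAF). CDKN2C, a cell cycle inhibitor, was at 336 ± 9.08 CPM in H929, at least 24000-fold higher than in OPM2, which had no count. PDGFB was at 163 ± 11.1 CPM and at least 11600-fold higher in H929. IGFBPL1 and PVR, the poliovirus receptor, were at least 8960-fold and 4330-fold lower in H929, with no count there. MYC (-0.46) and IRF4 (-0.50) were not called, and WHSC1 (-0.86) was under the fold threshold. Of the 43 interferon genes 33 were higher and 4 lower in H929 at an adjusted p under 0.05 (adjusted over the list alone, 33 and 4; camera adjusted p = 6.61e-06, and adjusted p = 0.698 with an estimated correlation). Line and any batch of its libraries cannot be told apart.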

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

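The tests of GC content in OPM2 dBRD9-A replicate 2, of its replicates set against each other, of RNA of H929 cells, of a scaling shift, of interferon genes by their level in DMSO and of interferon transcripts were chosen only after the result was seen, and the other tests of this part were planned before it.

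OPM2 dBRD9-A replicate 2 differed from its group mates more than any other library did from its own. A label swapped with a DMSO library is argued against by genes called in H929, whose median signed change was 1.125 in it, 1.022 and 0.902 in its group mates and at most 0.0414 in OPM2 DMSO, and RNA of H929 cells by 70 genes of H929 that OPM2 lacks, at 19.04 CPM against 26.2 and 20.2 in the mates and 8569 in H929 DMSO replicate 1. For lower depth the planned test decided nothing, since replicates 1 and 3 were measured against a mean that holds replicate 2 (SD 0.4473 after thinning to its depth, 0.4437 before, against 0.7925 for replicate 2), but a second version, chosen after that result, gave 0.1643 between replicates 1 and 3 after thinning and at least 0.773 between either and replicate 2, which argues against depth. GC-dependent yield as the whole cause is argued against by an SD of 0.5607 with the GC trend removed, against at most 0.309 elsewhere, while as part of the cause it stays open, since its R2 of 0.499 was not above 3 times that of the other libraries and the highest of these, 0.515, is a group mate measured against it. With replicates set against each other, GC took an R2 of 0.4771 and 0.5119 of the differences of replicate 2 from replicates 1 and 3. Between replicates 1 and 3 the R2 was 0.1146. The SD of the GC trend was 0.5596 in replicate 2 and at most 0.1516 in the other groups, where the R2 reached 0.3967. Replicate 2 thus varied more with GC, and whether yield was the reason was not tested. No biological explanation was tested for a single library.

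Ribosome biogenesis and MYC-associated genes were lower in both lines by camera at the preset correlation, and with an estimated correlation neither list was called (adjusted p = 0.292 each in OPM2 and adjusted p = 0.144 each in H929). Of 139 biogenesis factors 67 were called lower in OPM2 and 72 in H929. With the GC trend removed, the lists kept at least 81.6% of their medians (113.8% at most), which argues against GC content as the whole cause. One shift of all genes by scaling is argued against by cytosolic ribosomal proteins, whose median was 0.3208 higher than that of the biogenesis factors in OPM2 and 0.493 higher in H929. An effect of dBRD9-A or of less MYC may account for the pattern and stays open as a hypothesis, as no library separates the 2; of the 111 biogenesis factors not on the MYC list, 46 were called lower in OPM2 and 52 in H929.

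Interferon response genes were higher in both lines by camera at the preset correlation, and with an estimated correlation the list had adjusted p = 0.134 in OPM2 and adjusted p = 0.0469 in H929, the latter 0.229 without OPM2 dBRD9-A replicate 2. Of 43 members 24 were called higher in each line. For low counts the planned test decided nothing, since the treated libraries help to decide which members reach its mean of at least 1 log2 CPM (these kept 55.96% of the median of all members in OPM2 and 66.85% in H929). A split by the level in DMSO alone argues against low counts as the whole cause: the 14 members with a DMSO mean of at least 1 log2 CPM in OPM2 had a median of 0.7167, with 12 above 0, and the 27 in H929 had 0.8813, with 26 above 0, against an upper quartile of 0.2617 and 0.1784 over all genes at that level. GC content is argued against by at least 98.98% of the median being kept with its trend removed. Interferon transcripts made by the cells may be a source, but treated libraries held 3 to 36 counts of 21 interferon genes, too few to decide, so that this cannot be told apart from a direct effect of dBRD9-A.

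For genes, 10 splits of 6 libraries are too few for a share under 0.05. In OPM2, 1 of 10 splits gave as many called genes as the real one (2857, highest other 0), in H929 1 of 10 (2134, highest other 0) and between the lines in DMSO 1 of 10 (5960, highest other 0). For the shared genes 1 of 100 splits drawn of 200 gave as many (1142, highest other 18), which argues only against no response in either line. The highest other is the split with the H929 labels exchanged as a whole. The overlap of 2 independent responses is not what these splits draw, so they do not show whether the overlap is more than chance. For the difference of the responses 3 of 100 gave as many (95, highest other 4630), which decides nothing, since splits that mix treated and DMSO libraries put the responses themselves into the spread. With the H929 labels exchanged as a whole 4630 were called, where the difference becomes the sum of the 2 responses. With OPM2 DMSO replicate 1 grouped with dBRD9-A replicates 1 and 3 and the H929 groups as they are, 824 were called, and the whole H929 response stays in that difference. For the lists called by camera at the preset correlation, 2 of 10 splits gave as many in OPM2 (18, highest other 19). In H929 3 of 10 did (17, highest other 17), and both counts include the real split. The other splits, with no gene called, still gave at least 4 lists in OPM2 and 5 in H929. Splits that mix treated and DMSO libraries can thus give as many lists, so the number of lists does not set the treatment apart from a wrong grouping. These 10 splits are also too few for a share under 0.05. For the difference of the responses 71 of 100 splits gave as many lists (7, highest other 22), which decides nothing, since mixed splits put the responses into the spread.

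The response, H929 minus OPM2, differed by the edgeR interaction test for 21 named genes (log2). It was higher in OPM2 for CYSLTR1 (-4.09), LGALS3BP (-3.88), COL27A1 (-3.12), APOBEC3F (-2.53), PSD3 (-2.46), CDC14B (-2.38), OAS2 (-2.10), UBE2L6 (-1.70), CD68 (-1.60) and CFLAR (-1.27). It was higher in H929 for CAV1 (1.20), DTX3L (1.24), ITGA3 (1.26), SLC7A8 (1.48), TMEM173 (2.01), HBD (2.09), PTGER4 (2.28), AFAP1L2 (2.37), SH3PXD2B (2.60), ABCG2 (2.76) and SYNPO (2.90). All 21 but SH3PXD2B and ITGA3 had the lower mean CPM in DMSO in the line with the higher response. APOBEC3F, for example, was at 0.18 to 0.25 CPM in OPM2 DMSO libraries and 11.4 to 20.9 in those of H929. The same DMSO libraries enter the level and the response, so this does not test the starting level as a cause. By camera the response was lower in H929 for ribosome biogenesis factors (adjusted p = 0.0471) and bromodomain genes (adjusted p = 0.00367). It was higher for glycolysis (0.0357), cholesterol biosynthesis (0.00208), replication-dependent histones (0.00318), plasma cell genes (0.00318) and erythroid and megakaryocyte genes (0.0357). With an estimated correlation their adjusted p were 0.904 to 0.949, and fry called none of the 7 (0.407 to 0.717). Without OPM2 dBRD9-A replicate 2 camera kept 3 of the 7, cholesterol biosynthesis (0.00166), histones (0.0126) and plasma cell genes (0.00934), each with adjusted p = 0.956 at an estimated correlation. It no longer called ribosome biogenesis factors (0.579), bromodomain genes (0.176), glycolysis (0.105) or erythroid and megakaryocyte genes (0.105), and it called cytosolic ribosomal proteins (0.00219), oxidative phosphorylation (0.000658) and the unfolded protein response (0.000658) higher in H929, again with adjusted p = 0.956 each at an estimated correlation. SLC7A8 and TMEM173 were also named in H929.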

How the results depend on the processing

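The GC trend, the sum over transcripts, limma-voom and the omission of OPM2 dBRD9-A replicate 2 from results that do not contain it were chosen after the data were seen. The count of genes differing between the lines in DMSO stayed within 1.5 times under all 17 alternatives (4679 to 6405). The other gene counts did not. Called genes in OPM2 (2857) were 871 with its 6 libraries alone, 1729 with the replicate block, 4346 with the GC trend removed, 7243 with limma-voom and 1381 to 5277 with 1 library left out. Those in H929 (2134) were 4970, 1112, 3670 and 5910 in the same order, and 812 to 5946. Genes with a different response (95) were 372 with DESeq2, 26 with the block, 224 with the GC trend removed, 882 with limma-voom and 35 to 507 with 1 library left out. Shared genes (1142) were 1789, 574, 2128 and 3962, and 489 to 3352. Both the lowest and the highest of these ranges come from single libraries: OPM2 DMSO replicate 2 for OPM2, H929 DMSO replicate 2 for H929 and shared genes, OPM2 DMSO replicate 2 and H929 DMSO replicate 1 (35 each) for the difference, and OPM2 dBRD9-A replicate 2 for every highest value. Without OPM2 dBRD9-A replicate 2 the common coefficient of variation fell from 0.1855 to 0.1003, and with the GC trend removed to 0.1475. Limma-voom gave this replicate a weight of 0.054, against 0.523 to 2.53 for the other libraries. Whether these values account for the changed counts was not tested, and neither was the cause of the other changes. The lists called with an estimated correlation numbered 0 in OPM2, 1 in H929 and 0 for the difference, against 18, 17 and 7, with the cause not tested, and under the other 12, 13 and 18 alternatives run for lists their number stayed within 1.5 times (DESeq2, the filters, each line alone and limma-voom were run for genes only). The lists themselves changed: without OPM2 dBRD9-A replicate 2 the difference of the responses kept 3 of its 7 and gained 3, OPM2 kept 17 of 18 and gained 3, and H929 kept 16 of 17 and gained 1.

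By adjusted p alone, without the fold threshold of the lines in DMSO, 91 of 104 gene results were under 0.05, 74 of them under every alternative, and none of the 91 reversed. Of the other 13, 7 were under 0.05 in some alternative and 5 reversed, with the cause not tested. BRD7 in OPM2 was -0.14 without dBRD9-A replicate 2 and -0.094 with limma-voom, and 0.66 at most with 1 library left out. CRBN in OPM2 was -0.18 with the GC trend removed, -0.014 with limma-voom, and -0.068 to 0.086 with 1 library left out. IKZF3 in OPM2 was -0.0045 without a filter, -0.22 with the length trend removed, -0.070 with the GC trend removed, -0.037 with limma-voom, and -0.028 to 0.069 with 1 library left out. CRBN in H929 was 0.0503 with library size alone, and -0.055 to 0.045 with 1 library left out. IKZF3 in H929 was 0.0503 with library size alone, and -0.081 to 0.065 with 1 library left out. Replicate numbers were not seen to pair the samples: treated and DMSO replicates of one number correlated with 0.296, -0.0227 and -0.116 in OPM2 (highest for another number 0.198) and with -0.168 to -0.123 in H929 (highest for another number 0.52, 0.703 and 0.647), and 1 of 3 and 0 of 3 correlated best with their own number, so the block with the length trend was not run. In OPM2 the deviation of dBRD9-A replicate 2 enters these values, so they decide little there. In H929 libraries of unlike numbers varied together, which no fit took into account. Leaving out a library leaves its group with 2. In the simulation small changes were mostly missed: 1.5-fold changes were recovered for 13.4% of simulated genes in OPM2 and 11.9% in H929. It held 200 changed genes and called 106 and 101, against 2857 and 2134 here, so these shares need not hold for the data.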

Other observations

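The scan of gene families was chosen after values were seen, and the tests of host genes and of the starting level were written before their results.

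Members of further lists also fell. Of 47 translation factors 9 fell in OPM2 and 10 in H929 (camera adjusted p = 0.00176 and 2.58e-06, and adjusted p = 0.306 and adjusted p = 0.144 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases 8 fell in each line (adjusted over the list alone, 11 fell and 1 rose in OPM2 and 9 fell in H929; camera adjusted p = 0.000294 and 5.57e-05, and adjusted p = 0.292 and adjusted p = 0.144 with an estimated correlation). Of 77 mitochondrial ribosomal proteins 16 and 10 fell (camera adjusted p = 1.97e-05 and 3.03e-07, and adjusted p = 0.481 and adjusted p = 0.397 with an estimated correlation), and of 51 spliceosome genes 7 in each line (0.0126 and 1.34e-05, and adjusted p = 0.491 and adjusted p = 0.264 with an estimated correlation). Of 32 proteasome subunits 2 and 3 fell (camera adjusted p = 0.0312 and 0.00257, and adjusted p = 0.659 and adjusted p = 0.514 with an estimated correlation). Of 77 oxidative phosphorylation genes 10 fell and 1 rose in OPM2 (camera adjusted p = 0.004, and adjusted p = 0.659 with an estimated correlation) and 1 fell in H929 (0.113). Adjusted over the list alone, 10 and 17 translation factors and 18 and 14 mitochondrial ribosomal proteins fell in OPM2 and H929. For spliceosome genes these counts were 6 and 8, for proteasome subunits 0 and 2 and for oxidative phosphorylation genes 9 and 1. With OPM2 dBRD9-A replicate 2 left out, the numbers lower in OPM2 and H929 were 24 and 24 translation factors, 10 and 10 synthetases, 46 and 43 mitochondrial ribosomal proteins, 25 and 27 spliceosome genes, 8 and 11 proteasome subunits and 22 and 7 oxidative phosphorylation genes.

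In H929, of 24 glycolysis genes 2 fell (camera adjusted p = 0.00465, and adjusted p = 0.51 with an estimated correlation) and of 29 ATF4 targets 7 fell and 2 rose (camera adjusted p = 0.000853, and adjusted p = 0.45 with an estimated correlation). Of 24 cholesterol genes 2 fell (0.139), of 45 unfolded protein genes 1 fell (0.0687) and of 47 mitosis genes 1 fell (0.672; in OPM2 0.664). Adjusted over the list alone, none of the cholesterol and unfolded protein genes was called in H929. Of 14 B cell genes 1 rose (camera adjusted p = 0.0463, and adjusted p = 0.245 with an estimated correlation), of 9 myeloid genes 2 rose (0.0171, and adjusted p = 0.397 with an estimated correlation) and of 36 adhesion genes 7 rose and 2 fell (0.0478, and adjusted p = 0.51 with an estimated correlation). In OPM2, of 29 bromodomain genes 6 rose and 1 fell (camera adjusted p = 0.0147, and adjusted p = 0.502 with an estimated correlation). Its call was lost without OPM2 dBRD9-A replicate 2 (0.284), with a median of 0.11 against 0.36, and so was that of B cell genes in H929 (0.0941). In H929 the bromodomain list had adjusted p = 0.924.

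The lists below had no camera call in either treatment, with adjusted p in OPM2 and H929 of 0.231 and 0.647 for subunits found only in the non-canonical BAF complex, 0.987 and 0.467 for SWI/SNF subunits and 0.997 and 0.774 for the BCL2 family. They were 0.682 and 0.259 for MHC genes, 0.525 and 0.452 for NF-kB targets, 0.674 and 0.203 for immediate early genes, 0.0964 and 0.089 for lysosome and autophagy genes and 0.587 and 0.162 for cereblon and IRF4-MYC genes. They were 0.0683 and 0.129 for T and NK cell genes and 0.231 and 0.457 for erythroid and megakaryocyte genes. Of the lists called in H929, 4 were not called in OPM2: histones (0.585), B cell genes (0.865), myeloid genes (0.0745) and adhesion genes (0.761). Camera called lysosome and autophagy genes, without OPM2 dBRD9-A replicate 2, higher in OPM2 (0.00036, with 17 members higher against 6) and in H929 (0.0127, with 14 against 4), and myeloid genes in OPM2 (0.0149), and with an estimated correlation none of these was called. The fry test, which does not compare a list with other genes, called T and NK cell genes higher in both lines (0.00103 and 0.002) and, in OPM2, the subunits of the non-canonical BAF complex (0.00333) and lysosome and autophagy genes (0.0419). Of the lists that camera called, fry did not call oxidative phosphorylation (0.157) and proteasome subunits (0.0785) in OPM2 and glycolysis in H929 (0.0753). Results of 1 tested list are not given in any part.

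Between the lines in DMSO, genes higher in H929 at an adjusted p under 0.05 were 34 of 45 of the unfolded protein list and 14 of 29 ATF4 targets, with 4 lower in each (camera adjusted p = 0.021 each, and adjusted p = 0.793 and adjusted p = 0.95 with an estimated correlation). Of 24 cholesterol genes 17 were lower and 3 higher in H929 (0.0091, and adjusted p = 0.95 with an estimated correlation), and camera also called myeloid (0.0318, and adjusted p = 0.793 with an estimated correlation) and stromal and epithelial genes (0.0355, and adjusted p = 0.799 with an estimated correlation; 0.0944 without OPM2 dBRD9-A replicate 2). Each of these lists was also called by fry.

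Small nucleolar RNA entries were lower in both lines. They came first in a scan of 76 families of gene symbols with at least 20 members, SNORD and SNORA, so they were chosen after values were seen. Of 217 entries 25 were called lower in OPM2 and 34 in H929, and none higher, with medians of -0.62 and -0.69 (camera p = 1.12e-11 and 3.41e-14, and p = 0.155 and p = 0.128 with an estimated correlation). With OPM2 dBRD9-A replicate 2 left out, 52 and 114 were called lower and 1 and 0 higher. The medians were then -0.42 in OPM2 and -0.65 in H929. Some of these entries have equal counts, so they are not independent. Reads of the host genes may be the source: the changes of 162 entries and their 87 hosts correlated with a Spearman correlation of at least 0.4028 (0.4745 in OPM2), which fits reads from the hosts, although the host medians were smaller, -0.18 and -0.23. Small RNAs that changed along with their hosts would correlate in the same way, so the correlation does not show the source of the reads. Entries with the same host also share its value. Whether the small RNAs themselves changed was not measured, as these libraries select poly(A) RNA.

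Where the lines responded differently, a gene's starting level may play a part. The difference of the lines in DMSO replicate 1 and the difference of the responses, taken against DMSO replicates 2 and 3 and without OPM2 dBRD9-A replicate 2, correlated across 11467 genes with a Spearman correlation of -0.1051 and a Pearson's r of -0.2745. The first lies between the bounds written before the test, -0.3 for such a part and -0.1 against it, so the 2 cannot be told apart.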
